A study of Homo sapiens with 4 samples.

How the data were processed

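The series holds 4 Affymetrix PrimeView expression arrays, per the labels of the human breast cancer cell line Hs578T, of which 2 carry the label ELK3 knockdown and 2 the label sh control. Per the labels' protocols, lentiviral shRNA was used to make stable knockdown cells, total RNA was extracted with Trizol, and each RNA was amplified, labelled with biotin and hybridised to an array of its own. The knockdown arrays are numbered 1 and 5 and the control arrays 1 and 2 in the labels, which do not say whether a number stands for a construct, a clone or a culture. The p-values therefore measure the spread between these arrays. That spread may be technical, but between the knockdown arrays runs of neighbouring genes differed together, as given in the Results.

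The deposited table gives log2 signal values, one-colour and already normalized by the authors with RMA, per the submitters' processing notes. RMA usually corrects the background, equalises the distributions of the arrays and summarises the probes of a probe set by median polish; the version and the steps that were run are not given in the sources used here. The deposited log2 values cover 49293 probe sets per array, the medians of the arrays lie between 6.76 and 6.80, and no array's values are a copy of another's. An RMA table carries no call of signal above background, and a fold against a gene at the dim end is set partly by the floor of the array. Arrays have no read depth, so the number of arrays limits the precision.

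Probe sets were named through the platform's annotation table. It lists 46820 of the probe sets, 44988 with a single gene symbol and 1832 with several, and the other 2473 are unnamed here. No gene was named from a probe set with several symbols, and 0 symbols needed an update through the gene table of assembly GRCh38.p14, which also served to find which genes neighbour each other. Each of the 18132 genes was represented by the probe set with the highest mean over all 4 arrays; 11734 genes had more than 1 probe set. The choice of a probe set decides the direction of some genes, which are named where they occur.

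The groups were compared with limma 3.58.1 in R 4.3.3, with group as the only factor, lmFit and eBayes with an intensity trend, two-sided tests and Benjamini-Hochberg adjustment over all genes, at an adjusted p under 0.05. The fit had 2 residual degrees of freedom per gene and a prior of 4.83. With 2 arrays against 2 there are 3 distinct splits, so an exact permutation test of a single gene cannot give a p below 0.333. The selection in the series' design text (fold over 1.5 and unadjusted p under 0.05) was also counted. Folds are differences of log2 means turned back to the linear scale.

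A total of 30 gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists, and again with an estimated correlation. The fry test was run beside them; it asks whether the genes of a list move one way on balance and does not compare a list with other genes. Members past the threshold were counted over all genes tested and adjusted over the list alone. The named genes follow a rule: ELK3 and CXCL16; the 12 largest rises and 12 largest falls among genes past the threshold with no overlap between the groups; and up to 4 members by size of change of each list that passed and of 5 lists always reported (chemokine ligands, NK activating ligands, NK inhibitory ligands and checkpoints, mesenchymal markers and epithelial markers). Of the genes this rule names, 1 is not printed. Other genes are named in the text as the exceptions of a list or as examples of a family, and these were chosen after their values were seen. The groups, the main test, the lists, the naming rule and the alternatives were fixed before the data were examined.

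The fit was tested on simulated data with 200 changed genes among 18132 genes in 20 runs. It recovered 40.4% of genes changed 1.5-fold, 91.1% of those changed 2-fold and 99.7% of those changed 4-fold, with 4.56% false calls, and camera called 0 lists where no effect had been put in. The simulated noise was independent between genes, and far fewer genes were changed than in the data. The simulation therefore cannot tell how camera behaves where the genes of a list vary together. The alternatives tried were no intensity trend, robust moderation, no moderation, the mean of all probe sets of a gene, leaving out probe sets whose names mark cross-hybridisation, leaving out dim genes, quantile normalization, subtracting each array's median, other thresholds, testing each probe set, other list tests, and leaving out each array in turn. Windows of 50 neighbouring autosomal genes brighter than the median of all values (6.78) in both groups were summarised by their median difference and compared with 1000 shuffles of the gene order. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.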

Results

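RNA labelled as coming from Hs578T cells, a breast cancer line with mesenchymal features, was measured on 4 arrays. Per the labels, 2 came from cells with an shRNA against ELK3, which encodes an ETS family transcription factor of the ternary complex group, and 2 from sh control cells. The series addresses how ELK3 relates to CXCL16, a chemokine that attracts cells carrying the receptor CXCR6, and to killing by natural killer (NK) cells. All values are RMA log2 signals, and each gene is given as knockdown against control.

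ELK3 was lower in both knockdown arrays. Its signal was 8.09 and 7.92 in knockdown replicates 1 and 5, and 10.05 and 10.07 in control replicates 1 and 2. The mean fell from 10.06 ± 0.016 (SD, n = 2) to 8.00 ± 0.11 (SD, n = 2), which is 4.16-fold lower (log2 change -2.06, SE 0.09, limma adjusted p = 2.57e-06). The other ELK3 probe set fell by 2.04 on the log2 scale. CXCL16 rose from 8.03 ± 0.18 (SD, n = 2) to 8.71 ± 0.23 (SD, n = 2), or 1.60-fold (log2 change 0.68, SE 0.14, adjusted p = 0.00571). The probe sets read for ELK3 and CXCL16 both have names that mark cross-hybridisation. The other CXCL16 probe set rose by 0.44, or 1.36-fold. That rise is below the fold required by the selection in the series' design text. Larger rises were measured for 3028 genes (16.7% of those tested), and 554 genes (3.06%) had a larger fall than ELK3.

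Most genes on the lists of extracellular matrix and integrins (21 of 26), mesenchymal markers (22 of 23) and NF-kB targets (19 of 20) fell in the knockdown arrays. At an adjusted p under 0.05, 9219 of 18132 genes changed (50.8%), 5354 of them higher and 3865 lower in the knockdown arrays. The change exceeded 2-fold for 1843 higher and 1361 lower genes, and 16-fold for 108 higher and 146 lower genes. The groups did not overlap for any of the 9219 genes. With 2 arrays against 2, a gene that passes is nearly bound to be apart, so this adds no support. Over all genes the groups were apart for 75.3%, where chance gives 33.3%. The selection in the series' design text held 5753 genes, 3469 higher and 2284 lower.

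The 4 arrays formed 2 tight pairs. Over all probe sets, the knockdown arrays correlated at r = 0.996 and the control arrays at r = 0.998, against 0.902 to 0.904 between arrays of different groups. These correlations are across probe sets, which are not independent replicates. A difference of more than 1 log2 unit was found for 0.229% of probe sets between the knockdown arrays, for 0.0183% between the control arrays, and for 16.7% to 17.1% between arrays of different groups. The changes in each knockdown array against the mean of the controls correlated at r = 0.979, where unchanged arrays sharing those controls gave 0.333 in simulation. Their covariance was 1.12 against a simulated 0.00635, a difference of 1.12. The differences that share no array correlated at 0.970 and 0.968.

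**Figure D1:**
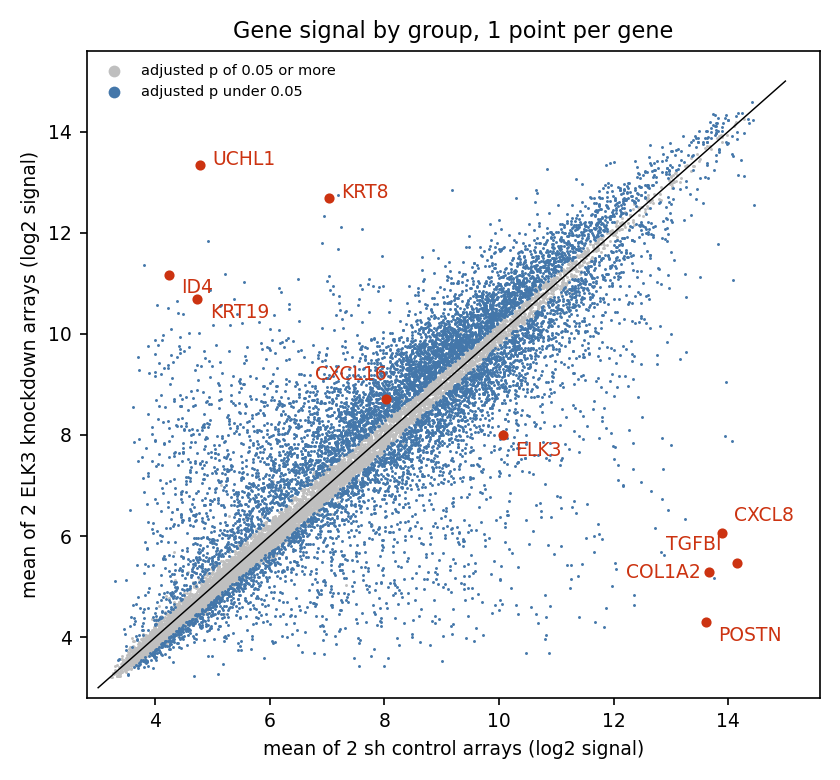
Mean log2 signal of each gene in the 2 knockdown arrays (vertical) against the 2 control arrays (horizontal), with the line of equal signal; blue points are genes with an adjusted p under 0.05. ELK3 lies below the line at 8.00 against 10.06, CXCL16 just above it at 8.71 against 8.03, and UCHL1 and POSTN at opposite far corners.

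The largest rises were those of UCHL1, a deubiquitinating enzyme abundant in neurons (378-fold, from 4.77 to 13.33, adjusted p = 3.74e-07), SHISA2, a modulator of WNT and FGF signalling (189-fold), ID4, an inhibitor of basic helix-loop-helix factors (123-fold), and GAL, the precursor of the neuropeptide galanin (121-fold). PM20D2 rose 92.8-fold, LIN28B, which blocks maturation of let-7 microRNAs, 78.8-fold, VAMP8, a vesicle fusion protein, 77.3-fold, and NMU, the neuropeptide neuromedin U, 64.3-fold. IRS2, an adaptor of the insulin receptor, and KRT19, an epithelial keratin, each rose 62.0-fold, and BEX4 rose 61.0-fold. In the control arrays the means of these 11 lay between 3.79 and 5.22.

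The largest falls were led by secreted matrix proteins. POSTN (periostin) fell 636-fold, from 13.61 ± 0.012 (SD, n = 2) to 4.29 ± 0.13 (SD, n = 2), with an adjusted p = 4.67e-08. TGFBI, a matrix protein induced by TGF-beta, was 412-fold lower, and the collagen genes COL6A3 and COL1A2 were 381-fold and 330-fold lower. CXCL8, the neutrophil chemokine interleukin-8, was 229-fold lower. The proteoglycan genes SRGN and LUM were 198-fold and 157-fold lower, CTHRC1 209-fold and THBS1, which encodes thrombospondin, 183-fold. PAGE5, a cancer-testis gene, fell 166-fold, the receptor tyrosine kinase gene AXL 154-fold and the mesenchymal cadherin gene CDH11 145-fold. The size of many of these folds rests on the probe set: for 16 of the 23 genes with the largest changes the fold moved by over 1.5 times with the mean of all probe sets or with cross-hybridising ones left out. On the log2 scale UCHL1 was then at 7.87, SHISA2 at 4.77, ID4 at 4.97, GAL at 7.81, IRS2 at 6.90, COL6A3 at -7.28, COL1A2 at -7.54, CTHRC1 at -4.84, THBS1 at -5.69, PAGE5 at -4.45, AXL at -5.16 and CDH11 at -3.25 with the mean. With cross-hybridising probe sets left out, PM20D2 was at 2.20, LIN28B at 2.46, POSTN at -8.54 and CXCL8 at -8.97. VAMP8, KRT19, BEX4, SRGN and LUM had 1 probe set each, so their folds could not move. Where a fold given for a list member moved as much, its log2 change under the choice that moved it most is given with it.

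**Figure D2:**
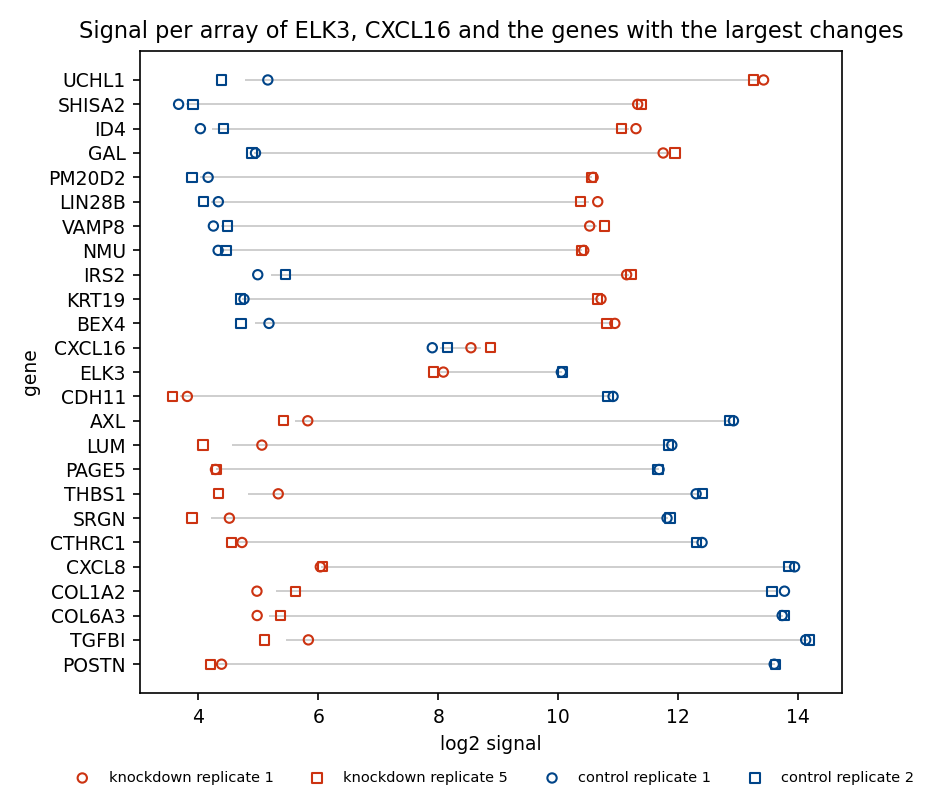
Log2 signal in each array for ELK3, CXCL16 and the genes with the largest changes that are printed here, with knockdown arrays in red and control arrays in blue and a grey line joining the group means. For every gene shown the arrays of the groups do not overlap, which the naming rule required of all but ELK3 and CXCL16. The gap is smallest for CXCL16, at 0.39.

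Mesenchymal markers fell almost as a whole. The exceptions named for this and the other lists were chosen after their values were seen. Of 23 measured, 22 fell and 1 rose, with the same counts when adjusted over the list alone (camera adjusted p = 4.02e-14, and adjusted p = 0.147 with an estimated correlation). Besides TGFBI, COL1A2 and AXL, the surface glycoprotein gene THY1 fell 124-fold. The exception was SNAI1, a repressor of E-cadherin, at 0.56. Of 26 extracellular matrix and integrin genes, 21 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 3.29e-11, and adjusted p = 0.147 with an estimated correlation). POSTN, COL6A3, THBS1 and LUM led it, and FBLN1, a fibulin, rose by 0.60. Matrix proteases and their inhibitors numbered 27, of which 20 fell and 1 rose (camera adjusted p = 1.64e-08, and adjusted p = 0.147 with an estimated correlation). Adjusted over the list alone, 20 fell and 2 rose. The sheddase gene ADAM12 was 77.5-fold lower, the urokinase gene PLAU 64.0-fold, the inhibitor TIMP3 42.3-fold and the stromelysin gene MMP3 39.0-fold, while TIMP4 rose by 0.83. ADAM12 was at -3.53 and PLAU at -5.26 with the mean of their probe sets, and TIMP3 at -4.81 with cross-hybridising ones left out. A second gene rose in this list without knockdown replicate 1, without knockdown replicate 5 or without control replicate 2, which made 2 in each case.

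Epithelial markers rose in part. Of 22 measured, 11 rose, 1 fell and 10 did not pass, also when adjusted over the list alone (camera adjusted p = 0.00261, and adjusted p = 0.188 with an estimated correlation). KRT19 and KRT8, keratins of simple epithelia, rose 62.0-fold and 50.8-fold, and OCLN, a tight junction protein, 6.65-fold. KRT7, another such keratin, was 7.22-fold lower. The adhesion genes CDH1 and EPCAM did not pass, with changes of -0.10 and -0.08. Basal breast markers numbered 11, of which 7 fell and 1 rose, or 8 and 1 adjusted over the list alone (camera adjusted p = 5.96e-04, and adjusted p = 0.182 with an estimated correlation). Among them NT5E, the ectonucleotidase CD73, was 110-fold lower, the hyaluronan receptor gene CD44 8.56-fold, the laminin gene LAMB3 7.07-fold and EGFR 5.26-fold, and ITGA6 rose by 1.43. With the mean of probe sets NT5E was at -5.01, LAMB3 at -1.83 and EGFR at -1.53. Luminal breast markers did not pass as a list (camera adjusted p = 0.256), with 5 of 17 higher and 1 lower, also when adjusted over the list alone. The 5 list members that rose were ID4, KRT19, KRT8, KRT18 and FOXA1, and the exception was MLPH at -4.60. ID4 counts here because the list fixed beforehand holds it, and whether it marks luminal cells was not tested. With the mean of probe sets FOXA1 was at 1.12 and MLPH at -2.02. ESR1 and GATA3 stood at -0.12 and 0.11. These shifts separate the same pairs of arrays that correlated at 0.902 to 0.904 with each other.

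Of 24 chemokine ligands measured, 9 fell, 2 rose and 13 did not pass, also when adjusted over the list alone (camera adjusted p = 5.67e-04, and adjusted p = 0.182 with an estimated correlation). The neutrophil attractants CXCL8, CXCL3 and CXCL2 were 229-fold, 51.1-fold and 37.8-fold lower, and the monocyte attractant CCL2 was 84.3-fold lower. CXCL2 was at -2.32 with cross-hybridising probe sets left out. Besides CXCL16, XCL1 rose (0.32); the call of XCL1 was lost without knockdown replicate 1 or control replicate 2, which left 1. Of the 4 genes for the CXCL16 receptor and shedding, ADAM10 and ADAM17, the proteases that release CXCL16 from the cell surface, changed by -1.08 and -0.71, and CXCR6 stood at -0.12 (1 higher and 2 lower, also when adjusted over the list alone; camera adjusted p = 0.305).

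Cytokines and growth factors fell in 21 of 31 genes and rose in 1, or 22 and 1 adjusted over the list alone (camera adjusted p = 1.30e-07, and adjusted p = 0.147 with an estimated correlation). INHBA, the activin A subunit, was 94.4-fold lower, IL6 62.6-fold, BMP2 18.0-fold and LIF 13.8-fold, and BMP4 rose by 0.95. IL6 was at -3.97 with the mean of its probe sets, and LIF at -2.20 with cross-hybridising ones left out. NF-kB targets fell in 19 of 20 genes and rose in 0, also when adjusted over the list alone (camera adjusted p = 2.22e-10, and adjusted p = 0.147 with an estimated correlation). CXCL8, CCL2, IL6 and CXCL3 led this list too, and CXCL1 was the member that did not pass (-0.27). Immediate early genes and targets of serum response factor (SRF), the partner of ELK3 on DNA, fell in 23 of 29 genes and rose in 1, or 23 and 2 adjusted over the list alone (camera adjusted p = 1.64e-08, and adjusted p = 0.182 with an estimated correlation). The tropomyosin gene TPM2 was 69.5-fold lower, the smooth muscle actin gene ACTG2 32.8-fold, the AP-1 subunit gene FOSL1 26.2-fold and the ERK phosphatase gene DUSP6 19.5-fold, and DUSP1 rose by 1.41. The mean of probe sets put TPM2 at -3.82, ACTG2 at -3.28 and FOSL1 at -3.40. Without knockdown replicate 5, 3 genes of that list rose. The 6 ETS ternary complex factors and SRF cofactors went both ways (camera adjusted p = 0.611), with MRTFB (1.05) and ELK1 (0.52) higher, ELK3, MRTFA (-0.79) and ELK4 (-0.55) lower and SRF at 0.29, or 3 and 3 adjusted over the list alone. SRF passed without knockdown replicate 5, at 0.45. With the mean of its probe sets ELK4 stood at -0.17 and did not pass. MRTFB stood at -0.10 and SRF at -0.07 with probe sets that mark cross-hybridisation left out.

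The list of NK activating ligands did not pass (camera adjusted p = 0.315). Of 19 measured, 5 rose and 7 fell, or 6 and 9 adjusted over the list alone. The CD27 ligand gene CD70 was 10.2-fold lower and the NKG2D ligand gene MICA 3.39-fold lower, while MICB, another NKG2D ligand, was 4.41-fold higher and NECTIN2, a ligand of DNAM-1, 3.14-fold higher. The rise of MICB was 0.43 and no longer passed with cross-hybridising probe sets left out, and NECTIN2 was at 0.85 with the mean of its probe sets. The other 3 that rose were CADM1 (1.15), BAG6 (0.60) and PCNA (0.53), which stands on the list as a ligand of NKp44 but is known to inhibit NK cells through it. Among the 7 that fell were also ULBP2 (-1.59), PVR (-1.49) and VIM (-1.16). ULBP2 stood at -0.12 and did not pass with cross-hybridising probe sets left out. NK inhibitory ligands and checkpoints fell in 10 of 18 genes and rose in 2, also when adjusted over the list alone (camera adjusted p = 0.0079, and adjusted p = 0.206 with an estimated correlation). The largest falls were those of HLA-C and HLA-B, which turned to 0.70 with the mean of probe sets and to 0.0068 with cross-hybridising ones left out, respectively. NECTIN3, an adhesion protein, was 2.91-fold lower and LGALS3, which encodes galectin-3, 2.10-fold lower. CLEC2D (0.86) and VSIR (0.52) were the 2 that rose, and without control replicate 1 the call of VSIR was lost (0.35) and the counts were 8 lower and 1 higher. With the mean of its probe sets VSIR did not pass either (0.28). CLEC2D stood at 0.19 and did not pass with cross-hybridising probe sets left out.

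Antigen presentation on MHC class I fell in 15 of 19 genes and rose in 1, also when adjusted over the list alone (camera adjusted p = 7.96e-06, and adjusted p = 0.182 with an estimated correlation). The immunoproteasome subunit genes PSMB8 and PSMB9 were 39.0-fold and 12.5-fold lower, and at -3.69 and -2.37 with the mean of their probe sets. The class I heavy chain genes HLA-C and HLA-B were 5.25-fold and 3.02-fold lower by their brightest probe sets, but the direction of both rests on the probe set: HLA-C was higher by 0.70 with the mean of its probe sets, and HLA-B by 0.0068 with cross-hybridising probe sets left out. The same holds for the gene that rose, the peptidase ERAP1 at 0.96, which was at -1.40 and -1.55 under those choices. Without knockdown replicate 1, 2 genes rose. Interferon response genes fell in 15 of 27 and rose in 4, also when adjusted over the list alone (camera adjusted p = 0.00174, and adjusted p = 0.407 with an estimated correlation). IFI44 was 10.2-fold lower, the transcription factor gene IRF1 7.89-fold and IFIT3 4.95-fold, while BST2, the tetherin gene, was 22.4-fold higher. IFI44 was at -1.56, IRF1 at -2.26 and BST2 at 3.80 with the mean of their probe sets. The other 3 that rose were IRF7 (1.56), IFIH1 (1.43, or 0.67 with that mean) and IFIT1 (0.56), and the call of IFIT1 was lost without control replicate 2 (0.50). The arrays behind these counts are the pairs that differ at 16.7% to 17.1% of probe sets by more than 1 log2 unit.

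Angiogenesis genes fell in 14 of 21 and rose in 3, or 14 and 4 adjusted over the list alone (camera adjusted p = 5.96e-04, and adjusted p = 0.182 with an estimated correlation). The ligand genes ANGPT1 and VEGFC were each 12.7-fold lower and the co-receptor gene NRP1 7.47-fold lower, beside THBS1, which inhibits angiogenesis. FLT1 (2.59), EFNA1 (2.11) and EFNB2 (0.56) rose, and EFNB2 lost its call with the mean of its probe sets (0.32). That mean put ANGPT1 at -2.77, NRP1 at -1.76 and FLT1 at 1.70. Hypoxia and glycolysis genes fell in 14 of 25 and rose in 3, or 15 and 4 adjusted over the list alone (camera adjusted p = 0.00464, and adjusted p = 0.190 with an estimated correlation). CA12, a carbonic anhydrase, was 13.3-fold lower, P4HA1, a collagen prolyl hydroxylase, 4.82-fold and PFKFB4 2.61-fold. ALDOC rose 3.52-fold, EGLN3 by 1.28 and TPI1 by 0.14, and without knockdown replicate 5 the number that rose was 5. CA12 was at -2.85 with the mean of its probe sets, and ALDOC at 0.56 with cross-hybridising ones left out. The call of TPI1 was lost under 5 alternatives, among them leaving out knockdown replicate 1, control replicate 1 or control replicate 2 (0.12, 0.13 and 0.15).

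Of 26 genes of the G2/M phase, 18 rose and 1 fell, or 19 and 2 adjusted over the list alone (camera adjusted p = 0.00292, and adjusted p = 0.423 with an estimated correlation). The largest rises were those of the phosphatase gene CDC25C (2.04-fold), the spindle gene DLGAP5 (1.88-fold), the checkpoint kinase gene BUB1 (1.86-fold) and the cyclin gene CCNB1 (1.78-fold), and CENPA changed by -0.52. Without control replicate 1 the number that rose was 10, and without knockdown replicate 1 the number that fell was 2, as it was after quantile normalization. Genes of G1/S and DNA replication did not pass as a list (camera adjusted p = 0.403), with 11 of 25 higher and 6 lower, also when adjusted over the list alone. Their median was 0.15 and their mean -0.03, and CCND1, the cyclin D1 gene, stood lowest at -3.67. Cell cycle inhibitors and p53 targets rose in 11 of 18 and fell in 4, also when adjusted over the list alone (camera adjusted p = 0.0488, and adjusted p = 0.404 with an estimated correlation). The CDK inhibitor gene CDKN1C rose from 5.56 to 9.56, CDKN2A, of the same kind, was 8.79-fold higher, while BBC3, a pro-apoptotic p53 target, and SESN1, a stress-induced one, were 8.63-fold and 8.16-fold higher. Taking the mean of probe sets put CDKN1C at 4.81, CDKN2A at 4.62 and BBC3 at 2.10. The 4 that fell were TP53I3 (-1.96), GADD45A (-1.88), GADD45B (-0.74) and FAS (-0.69), and FAS stood at 0.07 with cross-hybridising probe sets left out. That list's call was lost under 4 of 11 alternatives, among them leaving out knockdown replicate 5, and its adjusted p ranged from 0.0136 to 0.181.

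Cholesterol synthesis genes rose in 8 of 14 and fell in 1, or 9 and 1 adjusted over the list alone (camera adjusted p = 0.0193, and adjusted p = 0.541 with an estimated correlation). SC5D, a sterol desaturase, was 3.91-fold higher, HMGCS1, which makes HMG-CoA, 2.45-fold, DHCR7, which makes cholesterol from its precursor, 2.08-fold and FDPS 2.07-fold, while SQLE changed by -0.22. Its call was lost without knockdown replicate 5 and with dim genes left out, and the adjusted p ranged from 0.0043 to 0.0966 over 11 alternatives. The number that fell was 2 without knockdown replicate 5 and 0 without control replicate 1 or control replicate 2, where SQLE stood at -0.26 and -0.18. SQLE also lost its call without an intensity trend (-0.22). Genes of the unfolded protein and integrated stress response fell in 12 of 22 and rose in 3, or 14 and 3 adjusted over the list alone (camera adjusted p = 0.0275, and adjusted p = 0.251 with an estimated correlation). CHAC1, a glutathione-degrading enzyme, was 3.82-fold lower, VLDLR 1.90-fold, the chaperone gene DNAJC3 1.56-fold and the serine synthesis gene PSAT1 1.54-fold, and ATF4 (0.57), SESN2 (0.43) and SHMT2 (0.25) rose. The call was lost without control replicate 1, and its adjusted p ranged from 0.00577 to 0.0658. The number that rose was 5 without knockdown replicate 5 and 1 without control replicate 2, where SESN2 (0.41) and SHMT2 (0.22) lost their calls. SHMT2 also lost its call without control replicate 1 (0.28).

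The remaining lists did not pass with camera. Autophagy and lysosome genes had 5 higher and 11 lower of 17, also when adjusted over the list alone (camera adjusted p = 0.0768, and from 0.0204 to 0.0893 over 11 alternatives). It passed under 4 of these, among them leaving out either knockdown array. The 5 were GABARAPL1, ULK1, ATG5, LAMP2 and BECN1, of which LAMP2 lost its call with the mean of its probe sets (0.15). GABARAPL1 was at 2.74, and at 0.92 with cross-hybridising probe sets left out. Oxidative phosphorylation genes had 11 higher and 6 lower of 20 (camera adjusted p = 0.202), also when adjusted over the list alone. The number lower was 2 without control replicate 1 and also 2 without control replicate 2. Genes of oxidative stress and NRF2 had 7 higher and 9 lower of 18 (camera adjusted p = 0.305), also when adjusted over the list alone, with the detoxifying enzyme genes AKR1C1 and NQO1 lowest at -5.95 and -4.49. Death receptor and apoptosis genes had 8 higher and 7 lower of 22 (camera adjusted p = 0.923), also when adjusted over the list alone; their median was -0.03 and their mean 0.18, camera's direction was down and that of fry up.

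Immune cell markers had 2 higher (CD8A 0.85, NCAM1 0.68) and 2 lower (CSF1R -1.06, CD68 -0.78) of 17, also when adjusted over the list alone (camera adjusted p = 0.319). With the mean of its probe sets NCAM1 stood at 0.05 and did not pass. Endothelial markers had 1 higher (EGFL7 2.11) and 3 lower (PECAM1 -0.58, KDR -0.49, ESAM -0.35) of 11, or 1 and 2 adjusted over the list alone (camera adjusted p = 0.289). The number lower was 1 without control replicate 1, where KDR (-0.45) and ESAM (-0.36) lost their calls. ESAM also lost it without knockdown replicate 5 (-0.27) and without control replicate 2 (-0.35), and with the mean of its probe sets (-0.16). For this list camera's direction was down and that of fry up. Housekeeping genes had 4 higher and 5 lower of 11, also when adjusted over the list alone (camera adjusted p = 0.336). HPRT1 rose by 1.49, TBP by 0.91, GUSB by 0.88 and SDHA by 0.35, and TFRC (-1.38), B2M (-0.97), ACTB (-0.80), GAPDH (-0.29) and PGK1 (-0.25) fell. SDHA stood at -0.26 with cross-hybridising probe sets left out and at 0.19, not past, with the mean of its probe sets.

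**Figure D3:**
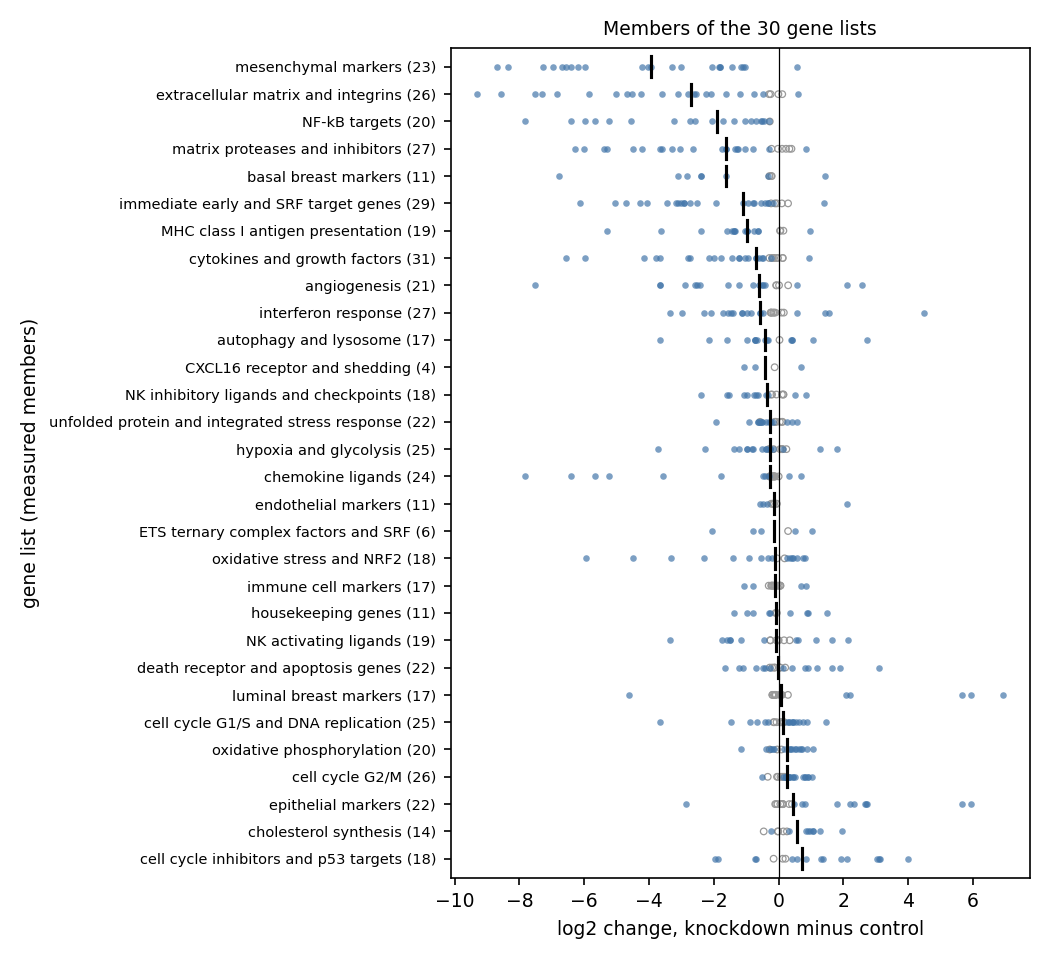
Log2 change of every measured member of the 30 gene lists, ordered by the list's median (black bar), with filled points for members at an adjusted p under 0.05 and open points for the others. Mesenchymal markers have the lowest median (-3.95), and cell cycle inhibitors and p53 targets the highest (0.72).

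Of the 30 lists, 18 passed with camera at the preset correlation, 14 lower and 4 higher, and 25 passed with fry. With an estimated correlation 0 passed after adjustment, and 6 had an unadjusted p under 0.05. Of the 391 list members past the threshold, 382 kept their call without knockdown replicate 1, 387 without knockdown replicate 5, 346 without control replicate 1 and 349 without control replicate 2. The labels do not say whether the 2 arrays of a group come from separate cultures, so every p here measures the spread between these samples, and the number of arrays limits the precision.

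Neighbouring genes shifted together between the groups. Over 172 windows of 50 neighbouring genes, the median differences ranged from -1.22 to 1.55 with an SD of 0.312, against at most 0.125 in 1000 shuffles of gene order (permutation p = 0.001, the smallest they can give). The highest was a window on chromosome 9 from DDX31 to MAN1B1, with 43 of 50 genes higher in the knockdown arrays. The lowest was on chromosome 8 from FBXO25 to LOXL2, with 47 of 50 genes lower. The SD was 0.0909 between the knockdown arrays, against at most 0.0333 in shuffles, and 0.0167 between the control arrays, against at most 0.0191. The spread between the knockdown arrays was therefore not independent from gene to gene, while that between the control arrays stayed within the shuffles. The p-values draw on both spreads, and the cause of the runs between the knockdown arrays was not tested.

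**Figure D4:**
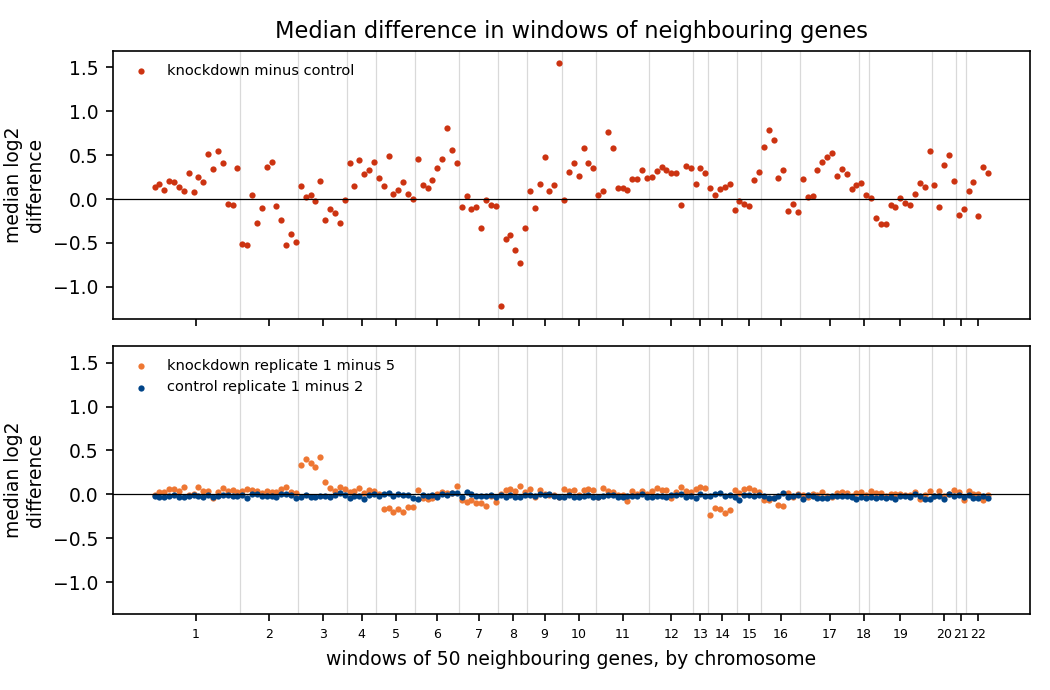
Median log2 difference in windows of 50 neighbouring genes in chromosome order, with knockdown minus control in the upper panel and the differences within each group in the lower panel. Group differences reach from -1.22 to 1.55, and windows on chromosome 3 stand up to 0.42 higher in knockdown replicate 1 than in replicate 5, and windows on chromosome 14 down to -0.24.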

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

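The comparison in this part was chosen after the table of probe sets had been seen. Probe sets that the annotation does not name lie outside the gene comparison, and they too differed between the groups. Of 2473, limma called 555 higher and 471 lower in the knockdown arrays at an adjusted p under 0.05 over all probe sets. Of all 49293 probe sets 24238 were called, which is a larger share than among the unnamed ones. The difference exceeded 4-fold for 38 higher and 42 lower probe sets. No explanation was tested for them.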

How the results depend on the processing

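All alternatives in this part were planned. Over them, 908 of 911 recomputed values of the genes named by rule, other than ELK3 and CXCL16, kept their direction and side of the threshold, as did 1139 of 1173 for the genes named after their values were seen and 317 of 328 for the lists. The genes named by rule were picked in these same arrays for large changes past the threshold, which favours a high count. Settings of the moderation also leave a log2 change as it was. ELK3 stayed between -2.14 and -1.98 and CXCL16 between 0.44 and 0.84, past the threshold in each of 13 alternatives; leaving out arrays put CXCL16 between 0.52 and 0.84. Changed genes numbered 7719 to 9673 without each array in turn; the lone array of a group was then assumed to vary like the pair. They numbered 24238 with each of 49293 probe sets tested, where more tests were made, and 5748 with a fold over 1.5 required, where the rule is stricter. The share of changed genes that were higher lay between 56.1% and 60.3%. Folds moved by over 1.5 times with the probe sets read for 44 of 83 genes named by rule and 19 of 109 named later. Genes with 1 probe set could not move. Without moderation the changed genes at an adjusted p under 0.05 numbered 5091, against 9219 in the main fit, and the design text's selection held 5280 genes. With an estimated correlation 0 lists passed, where 18 had; camera then refers its statistic to 2 degrees of freedom. With the mean of all probe sets, HLA-C turned to 0.70 and ERAP1 to -1.40. With cross-hybridising probe sets left out, HLA-B turned to 0.0068, ERAP1 to -1.55, MRTFB to -0.10, FAS to 0.068 and SDHA to -0.26; other probe sets were read, and the cause was not tested further. No paired analysis was possible because the groups share only replicate number 1. Signal over background was not given, so differences between dim genes are the least certain.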

Other observations

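The gene families, the counts of bright and dim genes, the windows of 25 genes and the windows within each group were chosen after values had been seen. The readings of the HEK293 marker test, the CDKN2A test and the normalization test were also changed after their values were seen, as told with them; the remaining tests in this part were set before their results were seen. Families are given as counts of members, and no family was tested against other genes. Among HOX genes, which pattern the body axis, 7 of 10 HOXB genes rose and 3 did not pass, with HOXB7 12.4-fold higher, and 5 of 7 HOXD genes rose, 1 fell and 1 did not pass, with HOXD13 12.1-fold higher. HOXC genes rose in 5 of 9 and 3 did not pass, with HOXC10 lower at -1.08, and HOXA2, the HOXA gene measured, did not pass (-0.03). Zinc finger genes with ZNF symbols rose in 224 of 451, fell in 53 and did not pass in 174, and ribosomal protein genes rose in 46 of 66, fell in 7 and did not pass in 13. Annexins rose in 3 of 12 and fell in 7, with ANXA3 48.5-fold higher and ANXA10 21.3-fold lower.

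Metallothioneins, which bind zinc and copper, fell in 7 of 8 genes and rose in 1, with MT1M 52.1-fold lower. S100A genes, which encode calcium-binding proteins, fell in 8 of 15, rose in 1 and did not pass in 6, with S100A6 47.0-fold lower. Aldo-keto reductases of the AKR1 family fell in 8 of 9, with AKR1C1 61.7-fold lower and AKR1C3 19.2-fold lower (-4.26, or -2.14 with the mean of its probe sets). All 3 measured tropomyosin genes fell, TPM1 by 3.01 (1.93 with cross-hybridising probe sets left out) and TPM4 by 2.79 on the log2 scale beside TPM2. Cancer-testis genes of the MAGE, PAGE, GAGE and XAGE groups fell in 8 of 25 and did not pass in 17, with MAGEA1 31.6-fold lower. Collagen genes fell in 19 of 43, rose in 2 and did not pass in 22, and protocadherin beta genes fell in 7 of 16, rose in 1 and did not pass in 8. Counting genes above 8.72 in one group and below 5.01 in the other, the upper and lower quartiles of all values, 59 genes were bright in the knockdown arrays and dim in the controls and 53 the reverse, against 0 between arrays of a group.

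The 9219 changed genes and the correlation of 0.902 to 0.904 between groups were weighed against technical and biological explanations. The authors' normalization is left open in part. The lower of the counts after quantile normalization and median subtraction was 9215, which under the bound written beforehand argued against it. These corrections moved the typical gene by 0.029 and 0.021, less than its SE of 0.10, so the counts by themselves decide nothing. The lower quartiles of the arrays lay between 4.98 and 5.05 and the upper between 8.69 and 8.75. Yet 1843 genes were over 2-fold higher and 1361 over 2-fold lower. A rescaling of whole arrays with such like quartiles cannot do this, so these values argue against it. Other steps of the normalization were not tested. A candidate explanation is that the groups hold cells with different genomes. The SD of the window medians was 0.312 against at most 0.125 in shuffles, although neighbours regulated together could shift in the same way. Some runs spanned a whole chromosome, and those given here were picked after their values were seen. Every window on chromosome 8 lay between -1.22 and -0.32, and every window on chromosome 4 between 0.15 and 0.44. Windows on chromosome 2 went both ways, from -0.52 to 0.42. Whether regulation of neighbours reaches that far was not tested. CDKN2A changed by 3.14, which under the bound written beforehand (2 or more) argued against a response to loss of ELK3 alone. The test rested on the gene being absent from the controls, because its locus is reported deleted in Hs578T. The control level of 7.80 by its brightest probe set (median of all values 6.78) does not show that absence. The test was therefore set aside once seen and decides nothing. CDKN2A changed by 4.62 with the mean of its probe sets, for which no control level is given here. The median change of 13 markers of HEK293, a candidate line, was 0.060, which under the bound written beforehand (0.3 or lower) argued against that line. Because the markers went both ways (SD 2.18), a condition on spread was added once seen, and the hypothesis is left open. With that condition only a median further below 0.3 than this SD could argue against the line, which made rejection very hard.

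Of these HEK293 markers, 5 were higher, 3 lower and 5 did not pass, the median lay at percentile 79.2 of 10000 random lists matched on mean signal, and 0 were on another list. Higher in the knockdown arrays were SOX11 (3.92, or 1.98 with the mean of its probe sets), NEFL (2.86), SALL2 (2.65), NES (2.63) and ZIC2 (0.99), and lower were TUBB3 (-3.13), ELAVL2 (-2.66) and SALL1 (-1.96, or -1.26 with that mean). In the knockdown arrays 7 of the 13 lay above the median of all values, and in the control arrays 5. MTAP, the neighbour of CDKN2A, was at 8.60 in the knockdown and 8.65 in the control arrays.

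Of the windows of 50 genes, 27 lay beyond the range of 20 shuffles, 15 above and 12 below. Windows of 25 genes gave an SD of 0.342 against at most 0.173. Within the knockdown group, windows on chromosome 3 from TRNT1 to PPP4R2 were 0.31 to 0.42 higher in replicate 1 than in replicate 5, while those on chromosome 5 from SKP2 to UIMC1 ranged from -0.20 to -0.15 and those on chromosome 14 from OR4N2 to ITPK1 from -0.24 to -0.15. The window differences within the knockdown group correlated at -0.065 with those between the groups, and the SD left after regression on them was 0.311.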
